A study of Homo sapiens with 16 samples.

How the data were processed

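HEK293 cells were profiled on 8 Agilent 2-colour arrays of 1 slide and 1 scan, in a loop in which each array held 2 of the 16 samples with opposite dyes. Group and replicate number were taken from the labels, and each group had 4 samples. Per the file headers, the deposited scanner files were made with Agilent Feature Extraction 10.7.3.1, and they hold linear intensity values per spot, namely the median pixel intensity, the median of the local background, and a processed intensity that was background-subtracted, spatially detrended and dye-normalized. Each array's scanner file was deposited for both of its samples, and the channel was taken from the dye that the labels give for a sample. The authors also deposited a table of log2 values, whose scale and centring were found from the values. Over 15462 bright probes its columns correlated with log2 processed intensities, centred on each probe's median, at r from 0.986 to 0.996, with column medians from −0.00869 to 0.0158 and a median of 0 over the samples for 96.3% of probes. The exact normalization of that table is not given in the sources used here, and it served as an alternative.

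The planned background correction used mean spot intensities, which the files do not hold, so median spot intensities were used. They were corrected with limma 3.58.1 in R 4.3.3 (normexp, offset 50), normalized by loess within arrays with control spots and spots marked as outliers at weight 0, and by the A-quantile method between arrays, and converted to 1 log2 value per channel. Net intensities were low: the median over spots well above background was 49.5 to 95.5 per sample, so the offset of 50 compresses folds, and log2 changes refer to corrected intensity plus 50. Spots marked as outliers (0.518% to 2.43% per sample) were left out, replicate spots were averaged, and 351 of the transcripts tested had a missing value. A probe was kept if its spots were well above background in at least 3 of 4 samples of at least 1 group, which left 18379 of 42405 probes. A gene with several kept probes (2736 genes) was represented by the probe with the highest mean.

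Probes were named by matching the array's accession, without version, to a RefSeq table of assembly GRCh38.p14, and 25771 probes (60.8%) matched 19740 genes. The array design refers to an older build, so no coordinates are given. Of 15171 transcripts tested, 11933 had a symbol and 3238 are unnamed here. No 2 samples were alike beyond noise: the smallest mean absolute difference between any 2 was 0.0902 on the log2 scale.

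One limma model was fitted to all 16 samples, with group and dye as fixed terms and the array as a random block (consensus correlation 0.37), followed by empirical Bayes moderation (11 residual and 3.2 prior degrees of freedom) and Benjamini-Hochberg adjustment over all transcripts tested. Tests were two-sided at an adjusted p of 0.05. The comparisons were TNFα against DMSO, Senexin A against DMSO, Senexin A with TNFα against TNFα, Senexin A with TNFα against Senexin A, and the interaction, which is the TNFα effect with Senexin A minus that without. Lower bounds written "at least" set the higher group's mean against the dim group's mean of, per sample, the higher of the lowest signal among probes well above background and the probe's own signal. List shifts were tested with camera (preset correlation 0.01), adjusted over 24 lists per comparison, and again with an estimated correlation.

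The 24 gene lists and the rule for named genes were fixed before the data were examined. The rule took the 10 largest rises and 10 largest falls that passed, up to 4 members per list that passed, and a fixed set of NF-κB, immediate early and Mediator kinase genes. Of 490 listed or fixed genes, 376 were tested. Alternatives fixed in advance were other background corrections and normalizations, filters, probe rules, array and dye terms, the replicate number as a block, variance priors, the authors' values, and leaving out each sample in turn. An offset of 1, and leaving out the 2 arrays of lowest signal (arrays 1 and 7, which hold DMSO replicate 1, Senexin A replicate 1, TNFα replicate 2 and Senexin A with TNFα replicate 2), were added after seeing the data.

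The model was tested on simulated data for 15171 transcripts with 50 changed at each fold. It recovered 80% at 1.25-fold, 98% at 1.5-fold and 100% at 3-fold for TNFα against DMSO, with 10 false among 198 calls, and 62%, 92% and 100% for the interaction, with 14 false among 189. False calls were most for Senexin A with TNFα against TNFα, 19 among 208. The folds were simulated on the scale of signal plus 50 with noise from the model, so the shares do not describe uncompressed folds of dim transcripts. Other packages were jsonlite 2.0.0 and statmod 1.5.0.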

Results

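RNA levels were measured on Agilent 2-colour whole-genome arrays in HEK293 cells, a human line derived from embryonic kidney. The 16 samples fell into 4 groups of 4: solvent (DMSO), Senexin A, TNFα, and Senexin A with TNFα. Senexin A is a selective inhibitor of the Mediator kinases CDK8 and CDK19, and TNFα is a cytokine that activates the transcription factor NF-κB. The inhibitor was given at 5 µM for 60 min, then TNFα at 10 ng/mL for 30 min, which made 90 min of inhibitor in all. The comparisons ask which transcripts TNFα changed, which transcripts the kinase inhibitor changed with and without TNFα, and whether the inhibitor altered the response to TNFα. Each of 8 arrays held 2 samples labelled with opposite dyes. In each sample, 44.4% to 51.9% of 58717 spots were well above their local background and 0 were saturated, and samples of one group correlated at r between 0.989 and 0.997 across transcripts. After a filter on dim probes, 15171 transcripts were tested, of which 11933 had a gene symbol. The number of arrays limits the precision. The labels do not say that the samples came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Changes are given as log2 fold change ± standard error (SE) of the background-corrected signal plus 50. This offset understates the change of dim transcripts, so folds of the scanner software's processed signals are given for leading genes. A fold is written "at least" where the lower group had no sample well above background.

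TNFα raised a small set of early response transcripts within 30 min, led by NFKBIA, IER3 and chemokine genes. NFKBIA, which encodes the NF-κB inhibitor IκBα, rose by 2.56 ± 0.03 (adjusted p = 9.1e-16), from a log2 level of 8.28 ± 0.13 (SD, n = 4) in DMSO samples to 10.83 ± 0.12 (SD, n = 4). On processed signals this was a 6.88-fold rise. IER3, an immediate early gene that modulates cell survival, rose by 1.87 ± 0.04 (adjusted p = 3.45e-13), or 5.28-fold on processed signals. The neutrophil-attracting chemokine genes CXCL1, CXCL2 and CXCL3 were well above background in 0 of 4 DMSO samples and in 4 of 4 TNFα samples. They rose by 1.71 ± 0.05, 1.45 ± 0.05 and 0.44 ± 0.03 (adjusted p = 8.27e-12, 5.62e-10 and 6.96e-06). Bounds from the group means, without the model's dye term, were at least 3.25-fold, 2.73-fold and 1.36-fold on the offset scale. The rise was by processed signals at least 50.02-fold, 36.9-fold and 8.78-fold (adjusted p on processed signals = 1.15e-10, 1.15e-08 and 6.58e-09).

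Of the 24 measured members of the NF-κB early target list, 7 rose and 17 did not pass (9 rose when adjusted over the list alone). The list shifted up relative to all other transcripts (camera adjusted p = 1.36e-19). Besides the 5 genes above, these were TNFAIP3, which encodes the feedback inhibitor A20 and rose by 0.20 ± 0.03 (at least 3.71-fold on processed signals), and CD83, which rose by 0.22 ± 0.03. NFKBIA and TNFAIP3 were also the 2 of 12 members of the NF-κB negative feedback list that rose, while 10 did not pass (2 rose when adjusted over the list alone; list shift up, adjusted p = 0.000364). In the chemokine and cytokine list, which shares CXCL1, CXCL2 and CXCL3 with the NF-κB list, those 3 of 10 members rose and 7 did not pass (4 when adjusted over the list alone; list shift up, adjusted p = 1.14e-09). CXCL8, ICAM1 and CCL20, classical NF-κB targets, had probes that were well above background in 0 samples and were not tested.

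Immediate early genes outside the NF-κB list rose too. Of 38 measured members of that list, 7 rose and 31 did not pass (15 rose when adjusted over the list alone; list shift up, adjusted p = 1.66e-14). JUN, which encodes an AP-1 subunit, rose by 0.81 ± 0.05 (adjusted p = 8.75e-07), and PPP1R15A, which encodes a phosphatase subunit of the stress response, by 0.56 ± 0.05. GADD45B rose by 0.53 ± 0.07 and EGR1, a zinc-finger transcription factor gene, by 0.41 ± 0.05. BTG2, ATF3 and IER2 rose by 0.39 ± 0.05, 0.39 ± 0.07 and 0.37 ± 0.06. MYC (−0.02 ± 0.04, adjusted p = 0.951) and FOS (0.10 ± 0.03, adjusted p = 0.371) did not pass. DUSP1, a phosphatase gene that restrains MAP kinases, rose by 0.52 ± 0.03. In its list, MAP kinase feedback, 1 of 13 members rose and 12 did not pass (2 rose when adjusted over the list alone; list shift up, adjusted p = 0.0104). The named transcripts that fell were DDIT4, an inhibitor of mTOR signalling, by 0.34 ± 0.05, and SCPEP1 by 0.31 ± 0.05. Falls also passed for TXNIP, a regulator of thioredoxin and glucose uptake, by 0.26 ± 0.04 and NAMPT, an enzyme of NAD synthesis, by 0.19 ± 0.03. ATF3, IER2 and CD83, and below MED13L, RGS16 and TNFAIP2, were chosen after their values were seen and were not refitted for these comparisons under the alternatives.

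In all, 21 transcripts passed an adjusted p of 0.05 for TNFα against DMSO (16 rose, 5 fell), and 1225 had an unadjusted p under 0.05 where chance gives 759. The count was 10 with each array as a fixed term, 13 without an array block, 9 when only these samples were fitted, 11 without the 2 arrays of lowest signal, and 13 without DMSO replicate 2 or without TNFα replicate 3. DDIT4 no longer passed without DMSO replicate 4 (−0.31) or TNFα replicate 3 (−0.32). SCPEP1, TXNIP and NAMPT no longer passed in 10, 10 and 9 of 16 leave-one-out fits. On processed signals SCPEP1 and NAMPT did not pass (adjusted p = 0.12 and 0.0752), and another SCPEP1 probe gave 0.04.

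**Figure D1:**
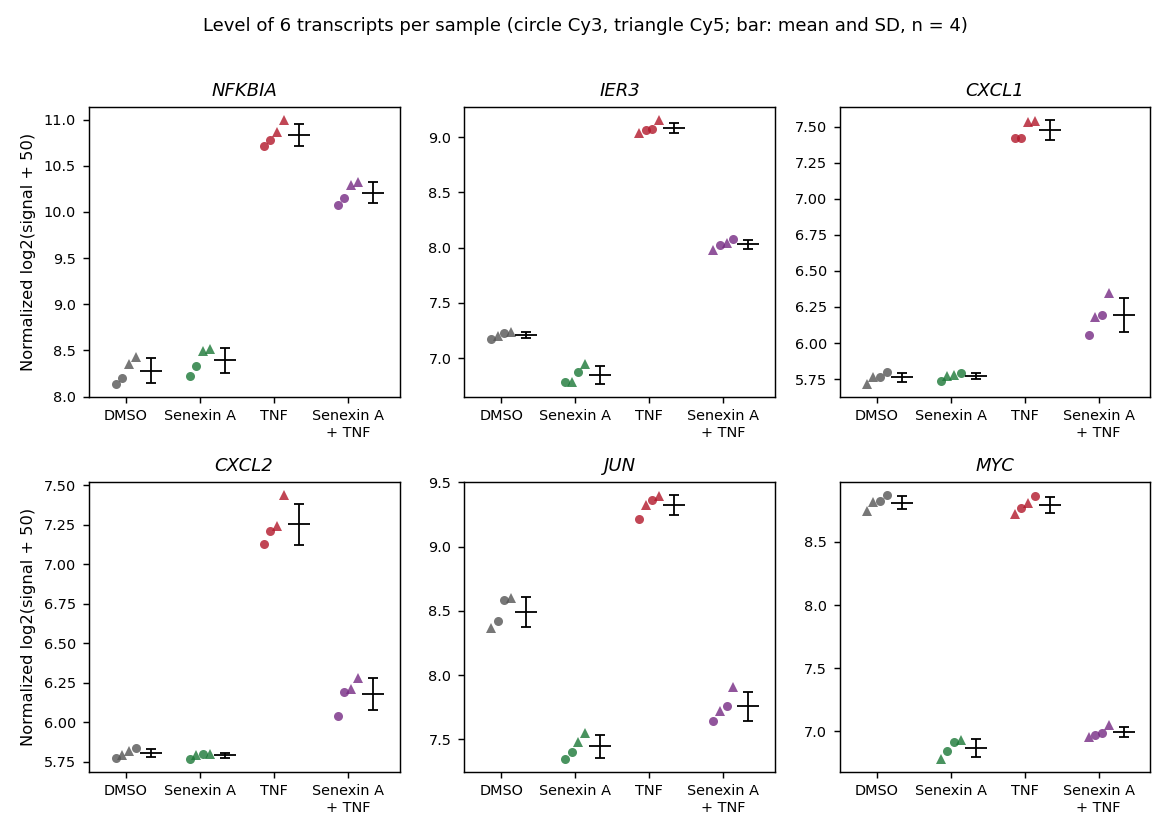
Normalized log2 level (signal plus 50) of 6 transcripts, with 1 point per sample by treatment group, circles for Cy3 and triangles for Cy5, and a bar for the mean and SD of 4 samples. CXCL1 averaged 5.76 in DMSO, 5.77 in Senexin A, 7.48 in TNFα and 6.20 in Senexin A with TNFα samples, while MYC averaged 8.81, 6.87, 8.79 and 6.99.

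Without TNFα, Senexin A mostly lowered transcripts. MYC, the proto-oncogene transcription factor, fell by 1.94 ± 0.04 (adjusted p = 1.09e-12), from a log2 level of 8.81 ± 0.05 (SD, n = 4) to 6.87 ± 0.07 (SD, n = 4), a 6.54-fold fall on processed signals. JUN fell by 1.04 ± 0.05 (adjusted p = 5.57e-08) and ADAMTS1, a secreted metalloprotease gene, fell by 1.01 ± 0.05 (adjusted p = 3e-08), which on processed signals were 2.55-fold and 2.69-fold falls. IRS2, an adaptor of insulin signalling, and PMAIP1, which encodes the pro-apoptotic protein NOXA, fell by 0.92 ± 0.07 and 0.90 ± 0.06. Among NF-κB targets, IER3 fell by 0.35 ± 0.04 (adjusted p = 0.000312), while NFKBIA changed by 0.13 ± 0.03 without passing (adjusted p = 0.188). The probes used for CXCL1, CXCL2 and CXCL3 were well above background in 0 samples of either group, while a further CXCL2 probe was so in 0 of 4 DMSO and 2 of 4 Senexin A samples and gave −0.02.

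Of 38 measured immediate early genes, 10 fell and 28 did not pass (21 fell when adjusted over the list alone), and the list shifted down (adjusted p = 5.02e-26). Beside MYC and JUN, TRIB1, a pseudokinase gene, fell by 0.88 ± 0.06, IER2 by 0.54 ± 0.06, EGR1 by 0.43 ± 0.05 and FOS by 0.16 ± 0.03. For EGR1 and FOS these were 2.03-fold and 2.09-fold falls on processed signals. Among 18 measured TGF-β and BMP targets, 3 fell and 15 did not pass (6 fell when adjusted over the list alone; list shift down, adjusted p = 5.17e-11). ID2 and ID4, which encode inhibitors of basic helix-loop-helix factors, fell by 0.76 ± 0.08 and 0.71 ± 0.06. HEY1, a repressor also on the Notch list, fell by 0.58 ± 0.05. With NRARP, a feedback regulator of Notch that fell by 0.61 ± 0.07, it made up the 2 of 9 Notch targets that fell, while 7 did not pass (5 fell when adjusted over the list alone; list shift down, adjusted p = 2.8e-08). In the heat shock list, 3 of 17 members fell and 14 did not pass (5 fell when adjusted over the list alone; list shift down, adjusted p = 1.32e-07). These were HSPA1B (−1.02 ± 0.08), HSPA1A (−0.95 ± 0.06) and the constitutive chaperone HSPA8 (−0.39 ± 0.05). HSPA1A and HSPA1B are nearly identical, so their probes may not tell them apart.

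In further lists that shifted, few members passed singly. In cholesterol synthesis, 2 of 22 members fell and 20 did not pass (4 fell when adjusted over the list alone; list shift down, adjusted p = 0.0169). They were INSIG1, which encodes not an enzyme but a brake on the sterol response, by 0.68 ± 0.07, and the isoprenoid enzyme gene IDI1 by 0.47 ± 0.07. HMOX1, the heme oxygenase gene, fell by 0.17 ± 0.03. Of 10 NRF2 and aryl hydrocarbon receptor targets it was the 1 that fell, and 9 did not pass (3 fell when adjusted over the list alone; list shift down, adjusted p = 2.04e-05). DUSP1 fell by 0.39 ± 0.03, as 1 of 13 MAP kinase feedback genes, and 12 did not pass (1 fell when adjusted over the list alone; list shift down, adjusted p = 0.000122). In the unfolded protein and integrated stress response list, DDIT4 (−0.38 ± 0.05) fell and 20 of 21 members did not pass (3 fell when adjusted over the list alone; list shift down, adjusted p = 0.0339). That shift had an adjusted p = 0.0849 with an estimated correlation. Among transcription elongation regulators, HEXIM1, an inhibitor of the elongation kinase P-TEFb, fell by 0.24 ± 0.04 and 18 of 19 did not pass (2 fell when adjusted over the list alone; list shift down, adjusted p = 0.047). Here the list had an adjusted p = 0.291 with an estimated correlation. The NF-κB negative feedback list shifted up (adjusted p = 0.0273, and adjusted p = 0.0568 with an estimated correlation). Over all transcripts 0 of its 12 members passed, and 1, NFKBIA, rose when adjusted over the list alone. RIPK1, a kinase of the TNF receptor complex, fell by 0.22 ± 0.04. TNFRSF1A, which encodes the receptor, did not pass (adjusted p = 0.992). The transcripts of the inhibited kinases and their partners did not pass: CDK8 changed by 0.02 ± 0.04, CDK19 by 0.02 ± 0.08, CCNC by 0.07 ± 0.05, MED12 by −0.07 ± 0.03 and MED13 by 0.04 ± 0.06.

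Of 69 transcripts past the threshold for Senexin A against DMSO, 64 fell and 5 rose, and 1241 had an unadjusted p under 0.05 where chance gives 759. The rises were MTRFR (0.33 ± 0.06), CLK1, a kinase of splicing factors (0.31 ± 0.04), ATP2B1 (0.27 ± 0.05), KDM4D (0.23 ± 0.05) and C19orf25 (0.22 ± 0.04). Further probes of CLK1 and C19orf25 gave 0.06 each. On processed signals CLK1 passed, while MTRFR, ATP2B1, KDM4D and C19orf25 did not (adjusted p = 0.223, 0.0739, 0.143 and 0.0968). The count was 42 without DMSO replicate 3, 36 without normalization between arrays, 35 without a dye term and 23 with each array as a fixed term. Without the 2 arrays of lowest signal the cholesterol and stress response lists no longer shifted (adjusted p = 0.0746 and 0.683). In leave-one-out fits KDM4D, RIPK1, FOS, MTRFR and ATP2B1 no longer passed in 9, 8, 7, 6 and 6 of 16 cases. Calls were also lost for HMOX1 without DMSO replicate 1 (−0.15) or 3 (−0.16) or Senexin A replicate 1 (−0.15) or 3 (−0.16), HEXIM1 without DMSO replicate 1 (−0.24) or Senexin A replicate 3 (−0.23), and C19orf25 without DMSO replicate 3 (0.19) or Senexin A replicate 1 (0.21).

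In TNFα-treated cells, Senexin A lowered several TNFα-raised transcripts, and it lowered MYC and JUN again. CXCL1 and CXCL2 were well above background in all 4 samples of both groups. They fell by 1.27 ± 0.05 and 1.08 ± 0.05 (adjusted p = 5.27e-10 and 2.1e-08), 6.44-fold and 5.77-fold falls on processed signals. IER3 fell by 1.03 ± 0.04, NFKBIA by 0.60 ± 0.03 and CXCL3 by 0.29 ± 0.03 (adjusted p = 7.31e-10, 7.91e-08 and 0.000355). MYC fell by 1.79 ± 0.04 and JUN by 1.56 ± 0.05 (adjusted p = 3.23e-12 and 3e-10), 5.58-fold and 3.66-fold falls on processed signals.

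Those chemokine genes, IER3 and NFKBIA were the 5 of 24 measured NF-κB early targets that fell, while 19 did not pass (9 fell when adjusted over the list alone; list shift down, adjusted p = 9.78e-12). TNFAIP3 changed by −0.11 ± 0.03 without passing (adjusted p = 0.094). In the chemokine and cytokine list 3 of 10 fell and 7 did not pass (3 when adjusted over the list alone; list shift down, adjusted p = 2.1e-06). Of 38 immediate early genes, 12 fell and 26 did not pass (20 fell when adjusted over the list alone; list shift down, adjusted p = 3.44e-29). Among them were TRIB1 (−0.84 ± 0.06), EGR1 (−0.58 ± 0.05) and the antiproliferative gene BTG2 (−0.34 ± 0.05). FOS changed by −0.14 ± 0.03 without passing (adjusted p = 0.0628), but on processed signals it passed with a 1.60-fold fall (adjusted p = 0.00643). DUSP1 fell by 0.44 ± 0.03 as 1 of 13 MAP kinase feedback genes while 12 did not pass (1 when adjusted over the list alone; list shift down, adjusted p = 0.00348).

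Most lists that shifted down without TNFα did so again, while the shifts of the stress response (adjusted p = 0.558) and elongation regulator (adjusted p = 0.154) lists did not pass. Of 18 TGF-β and BMP targets, 3 fell and 15 did not pass (6 fell when adjusted over the list alone; list shift down, adjusted p = 8.88e-08). The falls were ID2 by 0.80 ± 0.08, ID4 by 0.65 ± 0.06 and HEY1 by 0.45 ± 0.05. HEY1 and NRARP (−0.52 ± 0.07) were 2 of 9 Notch targets that fell, while 7 did not pass (4 fell when adjusted over the list alone; list shift down, adjusted p = 2.48e-05). Among 17 heat shock genes, 3 fell and 14 did not pass (3 fell when adjusted over the list alone; list shift down, adjusted p = 4.67e-05). They were HSPA1B by 0.80 ± 0.08, HSPA1A by 0.73 ± 0.06 and HSPA8 by 0.30 ± 0.05. INSIG1 (−0.70 ± 0.07), IDI1 (−0.44 ± 0.07) and HMGCS1, an enzyme of the mevalonate pathway (−0.39 ± 0.05), were 3 of 22 cholesterol synthesis genes that fell, while 19 did not pass. Adjusted over the list alone, 6 of them fell and 2 rose. The list shifted down (adjusted p = 0.0489), with adjusted p = 0.0631 with an estimated correlation. HMOX1 fell by 0.14 ± 0.03, as 1 of 10 NRF2 and aryl hydrocarbon receptor targets, and 9 did not pass (1 when adjusted over the list alone; list shift down, adjusted p = 0.00648). The Wnt target list shifted down (adjusted p = 0.0204) with 0 of its 12 members past the threshold and 0 when adjusted over the list alone. The Mediator kinase module list shifted up (adjusted p = 0.00948) with 0 of 6 members past the threshold over all transcripts. When adjusted over the list alone 2 rose, CDK8 (0.11 ± 0.04) and MED13L (0.22 ± 0.05), and a further CDK8 probe gave −0.02. ADAMTS1 and PMAIP1 fell by 0.95 ± 0.05 and 0.78 ± 0.06. HEXIM1 fell by 0.21 ± 0.04 and BBC3, which encodes the pro-apoptotic protein PUMA, by 0.22 ± 0.05.

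For Senexin A with TNFα against TNFα, 84 transcripts passed (77 fell, 7 rose), and 1270 had an unadjusted p under 0.05 where chance gives 759. The rises were TMEM205 (0.39 ± 0.07), SCARNA13 (0.31 ± 0.05), NUSAP1 (0.29 ± 0.05), CLK1 (0.29 ± 0.04), UPF1 (0.28 ± 0.06), NDUFB5 (0.26 ± 0.05) and MORN4 (0.21 ± 0.04), and a further CLK1 probe gave 0.07. On processed signals TMEM205, UPF1 and NDUFB5 did not pass (adjusted p = 0.127, 0.115 and 0.0707), nor did HSPA8 and BBC3 (adjusted p = 0.0518 and 0.149). Of the transcripts called in both Senexin A comparisons, 50 fell in both, where 0.325 would for independent lists, 1 rose in both, and 0 moved in opposite directions. The comparisons shared arrays but no sample. Across 15171 transcripts, which are not independent replicates, their log2 changes correlated at r = 0.42 with a covariance of 0.00288, against 0.15 and 0.000797 in 20 simulations with no effect. The simulations drew noise separately for each transcript. They therefore lack noise shared across transcripts and cannot show how far r varies by chance. The count was 51 without TNFα replicate 2 or 4, 48 without replicate 4 of Senexin A with TNFα, 28 with each array as a fixed term, and 211 (140 fell, 71 rose) when only these samples were fitted. It was 48 without the 2 arrays of lowest signal, which also ended the shifts of the Mediator kinase module (adjusted p = 0.316), NRF2 (adjusted p = 0.0695) and cholesterol (adjusted p = 0.122) lists. In leave-one-out fits UPF1, MORN4, HMOX1, NDUFB5 and BBC3 no longer passed in 13, 13, 13, 11 and 11 of 16 cases. Without TNFα replicate 2, BTG2 (−0.31), HSPA8 (−0.30) and TMEM205 (0.35) no longer passed. Calls were also lost for IDI1 without TNFα replicate 2 (−0.42) or 4 (−0.42) or double-treated replicate 4 (−0.38), and for HEXIM1 without TNFα replicate 2 (−0.16) or double-treated replicate 1 (−0.21), 3 (−0.20) or 4 (−0.21). The same held for NUSAP1 without TNFα replicate 2 (0.26) or 4 (0.29) or double-treated replicate 2 (0.23) or 4 (0.32), and for SCARNA13 without TNFα replicate 1 (0.28) or 4 (0.31) or double-treated replicate 2 (0.27) or 4 (0.32).

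**Figure D2:**
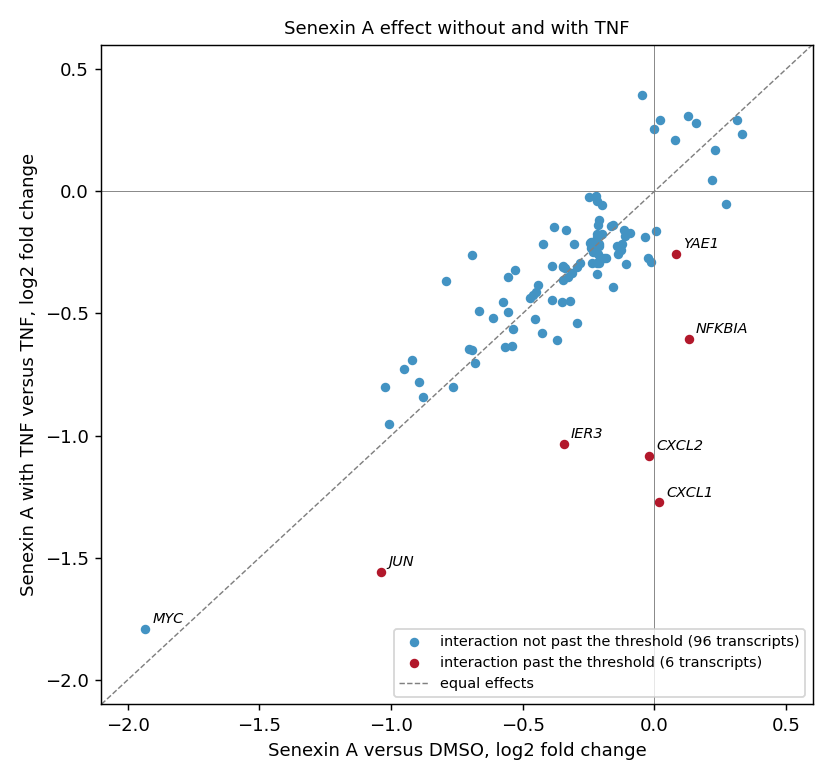
Log2 fold change by Senexin A without TNFα (horizontal axis) and with TNFα (vertical axis) for the 102 transcripts past the threshold in either comparison, with a dashed line for equal effects. The 6 transcripts whose effects differed by the interaction test are shown in red, and 95 of the 102 had the same sign in both comparisons.

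With Senexin A present, TNFα still raised NFKBIA and IER3, but fewer transcripts passed. NFKBIA rose by 1.83 ± 0.03 and IER3 by 1.18 ± 0.04 over Senexin A alone (adjusted p = 1.09e-13 and 2.16e-10), 4.01-fold and 3.31-fold on processed signals. CXCL1 rose by 0.42 ± 0.05 (adjusted p = 0.000967), from 0 of 4 samples well above background to 4 of 4. This was at least 1.34-fold on the offset scale and at least 7.81-fold on processed signals (adjusted p on processed signals = 3.21e-07). CXCL2 rose by 0.38 ± 0.05 (adjusted p = 0.015), a size that depends on the floor, since the probe used was well above background in 0 of 4 Senexin A samples. DUSP1 rose by 0.47 ± 0.03, PPP1R15A by 0.34 ± 0.05 and DUSP6, another MAP kinase phosphatase gene, by 0.19 ± 0.03. In all 7 transcripts rose and 0 fell in this limma fit, and 1138 had an unadjusted p under 0.05 where chance gives 759.

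Of 24 NF-κB early targets, 4 rose and 20 did not pass (6 rose when adjusted over the list alone; list shift up, adjusted p = 3e-08). In the chemokine and cytokine list 2 of 10 rose and 8 did not pass (3 when adjusted over the list alone; list shift up, adjusted p = 1.17e-05). Among immediate early genes 1 of 38, PPP1R15A, rose and 37 did not pass (14 rose when adjusted over the list alone; list shift up, adjusted p = 3.93e-13). JUN and EGR1 changed by 0.29 ± 0.05 and 0.25 ± 0.05 (adjusted p = 0.135 and 0.197). CXCL3 (0.17 ± 0.03, adjusted p = 0.189), which went from 0 of 4 samples well above background to 4 of 4, FOS (0.12 ± 0.03, adjusted p = 0.342) and TNFAIP3 (0.08 ± 0.03, adjusted p = 0.548) did not pass either. On processed signals CXCL3 (at least 3.55-fold), FOS (1.90-fold), EGR1 (1.53-fold) and TNFAIP3 (at least 1.90-fold) passed (adjusted p = 2.98e-06, 0.00131, 0.0433 and 0.0422). DUSP1 and DUSP6 were 2 of 13 MAP kinase feedback genes that rose, while 11 did not pass (2 when adjusted over the list alone; list shift up, adjusted p = 0.000323). The TNFα comparisons with and without Senexin A shared 6 raised transcripts, where 0.00738 would be for independent lists. Across transcripts their log2 changes correlated at r = 0.39, with a covariance of 0.0025, against 0.16 and 0.00083 in 20 simulations with no effect. These simulations too lack noise shared across transcripts, so they cannot show how far r varies by chance. The count was 4 without Senexin A replicate 1 or 2 or double-treated replicate 1, 2 or 3, 4 without the 2 arrays of lowest signal, and 14 on processed signals (12 rose, 2 fell). CXCL1 no longer passed with each array as a fixed term (adjusted p = 0.225) or when only these samples were fitted (adjusted p = 0.0799), and DUSP6, CXCL2 and PPP1R15A no longer passed in 13, 6 and 6 of 16 leave-one-out fits.

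The rise with TNFα was smaller in the presence of Senexin A for CXCL1, CXCL2, NFKBIA, IER3 and JUN, by the interaction test of the difference itself. The interaction, in log2, was −1.29 ± 0.06 for CXCL1, −1.06 ± 0.07 for CXCL2, −0.73 ± 0.04 for NFKBIA, −0.69 ± 0.05 for IER3 and −0.52 ± 0.07 for JUN (adjusted p = 5.03e-08, 1.87e-06, 6.95e-07, 6.71e-06 and 0.00739). IER3 kept 63.3% and NFKBIA 71.3% of the log2 rise seen without Senexin A, and 72.0% each on processed signals. For CXCL1 and CXCL2, whose probes used were not well above background in any sample without TNFα, no share is given, and the size of the interaction depends on the floor. CXCL1, CXCL2, IER3 and NFKBIA, which TNFα raised at least 1.5-fold on average over both conditions, had a median interaction of −0.90, against −0.15 over 17 raised transcripts without a minimum and −0.04 over 24 NF-κB early targets. On processed signals the interaction was −0.78 ± 0.07 for NFKBIA. Further probes gave −0.59 for CXCL1, −0.59 for CXCL2 and −0.54 for IER3.

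The other TNFα-raised transcripts did not pass this test over all transcripts. Of 17 transcripts that TNFα raised on average over both conditions, the interaction was −0.05 ± 0.04 for DUSP1, 0.03 ± 0.04 for DUSP6, −0.15 ± 0.07 for EGR1, −0.09 ± 0.08 for IER2 and 0.03 ± 0.08 for RGS16 (adjusted p = 0.951, 0.973, 0.86, 0.962 and 0.987). CXCL3 did not pass either, at −0.27 ± 0.04 (adjusted p = 0.0504), nor did GADD45B (−0.24 ± 0.09), PPP1R15A (−0.22 ± 0.07) or TNFAIP3 (−0.12 ± 0.03). Adjusted over the 17 raised transcripts, which were chosen on the same samples, CXCL3, GADD45B, PPP1R15A and TNFAIP3 had an adjusted p of 6.59e-05, 0.0303, 0.00988 and 0.00637. The fall of MYC with Senexin A did not differ detectably with TNFα (interaction 0.14 ± 0.05, adjusted p = 0.747). In the NF-κB early target list the interaction was negative for 4 of 24 members and 20 did not pass (7 negative and 1 positive, TNFAIP2, when adjusted over the list alone; list shift down, adjusted p = 4.58e-13). NFKBIA was the 1 of 12 NF-κB negative feedback genes, while 11 did not pass (2 when adjusted over the list alone; list shift down, adjusted p = 0.00148). CXCL1 and CXCL2 were 2 of 10 chemokine and cytokine genes, while 8 did not pass (3 when adjusted over the list alone; list shift down, adjusted p = 8.45e-06).

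In all, 6 transcripts passed the interaction test, each with a negative value, and 871 had an unadjusted p under 0.05 where chance gives 759. The remaining 1 was YAE1 (−0.34 ± 0.05, adjusted p = 0.018), which no longer passed in 12 of 16 leave-one-out fits. On processed signals 3 passed (CXCL1, CXCL2 and NFKBIA), and IER3 (−0.67 ± 0.11, adjusted p = 0.0579), JUN (−0.52 ± 0.12, adjusted p = 0.476) and YAE1 (−0.48, adjusted p = 0.195) did not. JUN was also lost with an offset of 1 (adjusted p = 0.293), with each array as a fixed term (0.0539), without the array block (0.152) and without a dye term (0.0892), which also ended the call of NFKBIA (adjusted p = 0.0599).

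**Figure D3:**
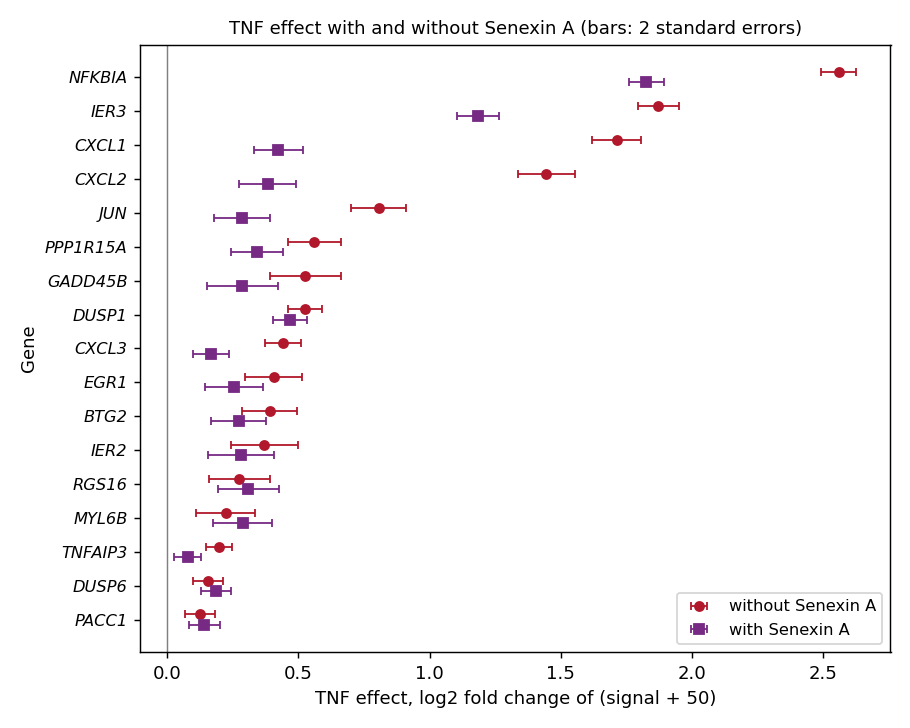
Effect of TNFα (log2 fold change of signal plus 50, horizontal axis) without Senexin A (circles) and with it (squares) for the 17 transcripts that TNFα raised on average over both conditions, with bars of 2 standard errors. The effect without and with Senexin A was 1.71 and 0.42 for CXCL1, 2.56 and 1.83 for NFKBIA, and 0.52 and 0.47 for DUSP1. The sizes for CXCL1 depend on the offset and the floor, since its probe used was not well above background in any sample without TNFα.

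Of 24 lists, 10 shifted in none of the 5 comparisons. The smallest adjusted p of each was 0.382 for core Mediator subunits (25 measured), 0.748 for SRF cytoskeletal targets (15 measured), 0.491 for TNF receptor pathway components (27 measured), 0.185 for interferon-stimulated genes (22 measured), 0.0673 for p53 targets (24 measured), 0.0885 for hypoxia-inducible genes (20 measured) and 0.141 for housekeeping genes (25 measured). The markers of other cell types gave 0.917 for leukocytes (5 measured), 0.558 for fibroblasts (3 measured) and 0.336 for keratin-rich epithelium (5 measured). Except for the 4 list shifts given with a second p, every list call above also held with an estimated correlation. The camera adjusted p was then larger, for example 0.000104 rather than 5.02e-26 for immediate early genes in Senexin A against DMSO.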

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

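The tests of the offset, of the 2 dim arrays and of the effect in unstimulated cells alone were chosen after the result was seen. The splits of the samples and the tests of scaling and of short-lived transcripts were written before.

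In 36 groups of 4 samples checked over 9 measures, 2 held a sample far from the others, where chance gives about 1 in 20. For CXCL2, Senexin A replicate 3 was lowest, at 5.769 against 5.795 to 5.799, with a gap of 0.874 of the group's range, and the CXCL2 probe used was well above background in 0 of these samples. For the share of spots marked as outliers, Senexin A replicate 3 was lowest, at 0.6591% against 0.8107% to 0.8192%, with a gap of 0.947 of the range.

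The effect of TNFα differed with Senexin A, by a test of the difference itself, for 6 transcripts. The log2 difference was −1.289 for CXCL1, −1.062 for CXCL2, −0.7336 for NFKBIA, −0.6875 for IER3, −0.5193 for JUN and −0.3367 for YAE1. The lists of NF-κB early targets (adjusted p = 4.58e-13), NF-κB negative feedback (adjusted p = 0.00148) and chemokines and cytokines (adjusted p = 8.45e-06) shifted down in this difference.

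Other splits of the samples tested whether chance gives as much. For the count of transcripts past the threshold, 1 of 35 splits, the real one, reached 21 for TNFα against DMSO (highest other 8), 1 of 35 reached 69 for Senexin A against DMSO (highest other 2) and 1 of 35 reached 84 for Senexin A with TNFα against TNFα (highest other 3). For Senexin A with TNFα against Senexin A 1 of 35 reached 7 (highest other 0), and for the difference 1 of 100 reached 6 (highest other 4). No other split thus gave as many transcripts. This does not exclude chance, since 1 of 35 is the smallest share such splits can give and the number of tests was not corrected for. Splits that mix the treatments also carry the treatment effect in their spread, which lowers their counts. For list shifts the real split alone, 1 of 35, reached 5 for TNFα against DMSO (highest other 4). The same was so for Senexin A against DMSO (10, highest other 6) and Senexin A with TNFα against TNFα (11, highest other 6). The same limit holds here, and other splits still shifted up to 4 or 6 lists, so chance is not excluded for single lists. Chance cannot be excluded for the number of lists shifted by TNFα with Senexin A present (3 of 35 reached 4, highest other 4) or in the difference (22 of 100 reached 3, highest other 7). Nor can it for the median difference of −0.8976 (5 of 100 draws as far from 0, highest other −1.028), although 3 of those 5 draws, the real one included, keep the grouping of the TNFα-treated samples.

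Weighed first was the smaller rise with TNFα under Senexin A. Compression of dim signals by the offset of 50 cannot be the whole cause, since 5 of 5 genes (CXCL1, CXCL2, NFKBIA, IER3 and JUN) kept a difference below −2 SE on processed signals and with an offset of 1, though JUN and, on processed signals, IER3 then missed the threshold. Nor does the difference rest on the 2 dim arrays alone, since without them 5 of 5 genes kept a difference below −2 SE (from −0.5534 for JUN to −1.358 for CXCL1). In both tests the 5 genes had been chosen on the same samples, so neither tests the calls anew. An effect of Senexin A on unstimulated cells alone is argued against for NFKBIA and, more narrowly, for IER3 and JUN. Without TNFα its change was at least 0.1294 under 3 settings of the same samples, without passing in the main fit (adjusted p = 0.188). With TNFα NFKBIA fell by 0.6042. IER3 and JUN fell with Senexin A already without TNFα (adjusted p = 0.000312 and 5.57e-08). For these genes this explanation was not tested and stays open. It cannot be told apart for CXCL1 and CXCL2, whose probes were well above background in 0 DMSO samples. An action of Senexin A on the response itself stays open, untested beyond these comparisons.

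The other pattern weighed was that transcripts mostly fell with Senexin A. A shift shared by all transcripts is argued against only for the largest changes. Of transcripts 1.5-fold or more from the median of all transcripts, at least 90% lay below it under 2 normalizations. In the main fit 20 lay below and 0 above without TNFα, and 19 and 0 with it. Without normalization between arrays these were 15 and 0, and 18 and 2. The medians were already near 0 after normalization (−9.51e-05 to 0.00694), so centring on them changed little, and smaller changes were not covered. A general loss of short-lived transcripts, as after a block of transcription, cannot be told apart from a selective effect: 4 of 38 immediate early genes had a 95% interval above a fall of 10% on processed signals, where at least 5 were set as the number that would exclude it, and 23 had an interval below 0. Whether the falls came through CDK8 and CDK19 was not tested, since no second inhibitor or kinase-deficient cell was measured.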

How the results depend on the processing

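An offset of 1 and leaving out arrays 1 and 7 were chosen after seeing the data. Of 91 calls for named genes, 43 passed under every alternative that gave a value for them (30 to 32 each) and 63 in all 16 leave-one-out fits, and 0 changed direction. The most were lost with each array as a fixed term (43), without normalization between arrays (33), without arrays 1 and 7 (32, with fewer samples) and without a dye term (30).

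The following counts and medians moved beyond 1.5 times or the spread, and the cause was not tested unless stated. A 1.5-fold minimum, which removes smaller changes, left 5 of 21 transcripts for TNFα against DMSO, 16 of 69 for Senexin A against DMSO, 19 of 84 for Senexin A with TNFα against TNFα, and 2 of 7 for Senexin A with TNFα against Senexin A. Each array as a fixed term gave 10, 23 and 28 for the comparisons of TNFα with DMSO, Senexin A with DMSO, and the double treatment with TNFα. No array block gave 13 for TNFα against DMSO and 49 for the double treatment against TNFα. Fitting only the groups compared gave 9 and 211 for the same pair, and 3 for the double treatment against Senexin A. The 211 (71 rose, 140 fell) included all 84. Without normalization between arrays the Senexin A comparisons gave 36 and 41, and without a dye term 35 and 42. Without arrays 1 and 7 (fewer samples) the counts were 11 for TNFα against DMSO, 48 for Senexin A with TNFα against TNFα and 4 for Senexin A with TNFα against Senexin A. Senexin A with TNFα against Senexin A gave 14 on processed signals (12 rose, 2 fell; 7 list shifts, against 4), 12 on their 75th-percentile scaling, 15 with the authors' values and 4 with the filter asking for all samples. The interaction count of 6 was 3 on processed signals, 3 with the 75th-percentile scaling, 3 with the authors' values and 3 without a dye term.

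The median interaction of −0.8976 depends on which genes are taken. It was −0.7336 for genes chosen by TNFα against DMSO alone, −0.03906 over the NF-κB early target list, −0.1512 without a fold minimum, −0.598 on processed signals, −0.5973 with the 75th-percentile scaling, −0.6781 with an offset of 1, −0.6086 with the authors' values, −0.7106 with the filter asking for all samples and −0.7787 with the mean of all kept probes.

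Leaving out each sample in turn gave 13 to 23 transcripts for TNFα against DMSO (13 without DMSO replicate 2 or TNFα replicate 3) and 42 to 76 for Senexin A against DMSO (42 without DMSO replicate 3). It gave 48 to 82 for Senexin A with TNFα against TNFα (51 without TNFα replicate 2 or 4, 48 without double-treated replicate 4). For Senexin A with TNFα against Senexin A it gave 4 to 9 (4 without Senexin A replicate 1 or 2 or double-treated replicate 1, 2 or 3), for the interaction 5 to 6, and for its median −0.9216 to −0.8645. With replicate number as the block the counts were 17, 67, 66, 5 and 5, and whether the numbers pair the samples stays open. The mean r of residuals was 0.046 over 20 pairs of samples with the same number on different arrays against −0.0619 over 68 with different numbers, and on the same array 0.573 against 0.332 over 4 pairs each. Fitting only the groups compared cannot give an interaction. Signal over background limits CXCL1, CXCL3 and the CXCL2 probe used, which were at background without TNFα, and any transcript under that level in every group.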

Other observations

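The genes in this part were chosen after their values were seen, no explanation for them was tested, and their calls were not refitted under the alternatives.

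Senexin A lowered several further transcripts both without and with TNFα. CXCR4, which encodes a chemokine receptor, fell by 0.69 ± 0.04 without TNFα (adjusted p = 6.57e-08) and by 0.65 ± 0.04 with it (adjusted p = 8.15e-08), with an interaction of 0.04 (adjusted p = 0.965). TXNIP, which limits thioredoxin and glucose uptake, fell by 0.67 ± 0.04 and 0.49 ± 0.04 (adjusted p = 1.37e-06 and 2.8e-05), and its paralog ARRDC4 by 0.28 ± 0.03 and 0.30 ± 0.03. The glucocorticoid-inducible gene TSC22D3 fell by 0.53 ± 0.06 and 0.32 ± 0.06, the CBP/p300-binding gene CITED2 by 0.35 ± 0.04 and 0.36 ± 0.04, and DEPP1 by 0.21 ± 0.03 and 0.29 ± 0.03.

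Among transcription factor genes, FOXQ1 fell by 0.54 ± 0.05 and 0.57 ± 0.05, and SOX4 by 0.31 ± 0.06 and 0.34 ± 0.06. The Wnt receptor genes FZD8 and FZD4 fell by 0.44 ± 0.07 and 0.20 ± 0.03 without TNFα, and by 0.38 ± 0.07 and 0.17 ± 0.03 with it. GAS1, which encodes a hedgehog co-receptor, fell by 0.45 ± 0.05 and 0.52 ± 0.05. RGS16, a regulator of G-protein signalling that TNFα raised on average over both conditions, fell by 0.45 ± 0.06 and 0.41 ± 0.06. BCL2L11, which encodes the pro-apoptotic protein BIM, fell by 0.24 ± 0.04 and 0.21 ± 0.04 (adjusted p = 0.0157 and 0.0424).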
